A study of Rattus norvegicus with 6 samples.

How the data were processed

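RNA was measured in dorsal root ganglia, the clusters of sensory neuron cell bodies beside the spinal cord, of rats 7 days after a sham operation (3 libraries) or a partial sciatic nerve ligation (pSNL, 3 libraries). In pSNL a part of the sciatic nerve is tied tightly, which leaves injured and spared axons in the same nerve and is used as a model of neuropathic pain. Per the labels, ganglia were frozen on dry ice, RNA was taken with Trizol, and libraries were built from 1 µg of total RNA with a BGISEQ-500 kit. The labels' protocols also name Illumina preparation, so the sequencer is left open here. Group and replicate number came from the sample titles. The labels do not say that each library is a separate animal, so p-values measure the spread between these libraries, which may be partly technical.

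The deposited files hold, per the file headers, an expected count, an FPKM value and a length for each gene, with 1 file per library. The expected counts were estimated by the authors and need not be whole, and 89.1% to 89.5% of them were whole. FPKM was computed by the authors from those expected counts and the gene length in the deposited files, and the library totals it implies lie between 4328590 and 4435078. The submitters' processing notes name CASAVA 1.4 and Bowtie2. The quantifier, genome build and annotation are not given in the sources used here, so no coordinates are reported. Only genes with a value above 0 are listed in a file, and a gene absent from a file was taken as 0. The files list 14346 genes in at least 1 library and 12211 in all 6. Gene identifiers were matched to symbols in a RefSeq gene table of the assembly GRCr8, used for names only; 14227 matched by gene ID, 11 by transcript accession, and 108 were kept by ID. Whether counting used strand is not given in the sources used here, and reads of close paralogs, such as the RT1 class II genes and the haemoglobins, may be split between copies by the estimate.

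Expected counts were rounded to whole numbers. FPKM values were used only to check the totals. The libraries held 4412391, 4405639 and 4310643 counts in sham replicates 1 to 3 and 4349668, 4339565 and 4416121 counts in pSNL replicates 1 to 3, so 1 CPM, the unit of read counts normalised to library size, is 4.31 to 4.42 counts before scaling, and genes of a few CPM carry a large counting error. Counting intervals given for genes with at most 3 sham counts are exact 95% intervals on counts summed over the libraries of each group. They therefore cover counting error only and leave out the spread between libraries. Reads carry no molecular identifiers, so duplicate reads may make these intervals too narrow as well.

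The comparison of pSNL with sham used edgeR 4.0.16 in R 4.3.3, with TMM factors, edgeR's default filter on low counts, a robust quasi-likelihood fit and its F test, and Benjamini-Hochberg adjustment over the tested genes, with an adjusted p of 0.05 as the threshold. Standard errors of log2 fold changes were derived from the test statistic. Values per library are CPM on TMM-scaled library sizes, and means are given ± SD over 3 libraries. Before the data were examined, 37 gene lists were fixed, covering injury genes, neuropeptides, ion channels and receptors, neuron types, glia, immune cells, connective tissue, vessels, blood, and tissues that dissection could include. The 33 lists with at least 5 tested members were tested with camera (limma 3.58.1, two-sided, preset inter-gene correlation of 0.01), again with the correlation estimated from the data, and with fry, which asks whether the genes of a list move on balance 1 way. Each list's mean log2 CPM (prior count 2) per library was compared with an exact two-sided permutation test, in which 3 libraries against 3 cannot go below p = 0.1. Of the listed genes 528 were tested, and 49 listed genes are in at least 2 lists. Members were also adjusted over each list alone. Those calls are not corrected across the 37 lists, so the threshold of 0.05 does not hold over all lists together. Genes were named by a rule fixed at the same time. It takes the 8 largest rises and falls among genes past the threshold with at least 1 CPM in the higher group, a gene symbol and no overlap between groups, 6 known injury genes as a check of the labels (Atf3, Gal, Npy, Sprr1a, Sox11 and Gap43), and up to 4 members with the smallest p in each list described, with any member needed to describe a count of at most 5. Some results that the rule would name are not reported here.

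The fit was tested on simulated counts drawn from the means and sizes of these libraries, in which 200 genes were changed before the filter on low counts. Of the 10959 genes that passed it, 67 were changed 1.41-fold, 65 were changed 2-fold and 64 were changed 4-fold. The fit called 20.9%, 67.7% and 93.8% of these, with 12 false calls. A shifted list was recovered and 0 of 20 unchanged lists were called. The simulated genes varied independently of each other. This therefore does not show how camera behaves where the genes of a list vary together, as in these libraries (estimated correlation 0.57 for injury genes). The changed genes were picked at random, so the shares called need not hold for genes that vary widely between libraries. Gal, for example, was 17.3-fold higher in pSNL and was not called (edgeR adjusted p = 0.0891). Replicates were compared before averaging. Their counts differed by more than sampling noise in each pair, so no library was counted as a repeat. The chi-square per degree of freedom was 2.87 between sham replicates 1 and 2, and 7.35 to 13.8 in the other pairs. Such a spread can also be technical, so it does not show that each library is a separate animal.

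Alternatives fixed at the start were DESeq2 size factors, upper-quartile factors, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-trend, the replicate number as a block, leaving out each library, other thresholds, and other list tests. A fit without robust dispersion, and a fit without replicate 3 of both groups, were chosen after seeing the data. Tables were prepared with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures with matplotlib 3.10.9.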

Results

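Gene expression was measured by RNA sequencing in rat dorsal root ganglia 7 days after partial sciatic nerve ligation (pSNL) or a sham operation, with 3 libraries in each group and 4310643 to 4416121 estimated counts per library. The comparison asks which genes of the ganglion differ after peripheral nerve injury. Between 13135 and 13343 genes were listed per library, and 11091 passed the filter on low counts.

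The 6 injury genes fixed as a check of the labels were all higher in each pSNL library than in each sham library. Atf3, a transcription factor induced in injured neurons, was at 16.7 ± 5.69 CPM in sham and 209 ± 101 CPM in pSNL (SD, n = 3 each), and the neuropeptide galanin (Gal) was at 15.5 ± 12.5 and 269 ± 76.2 CPM. Neuropeptide Y (Npy) was at 23.8 ± 15.1 CPM in sham and 189 ± 76.3 CPM in pSNL. These genes varied widely between libraries and did not pass the threshold in edgeR's quasi-likelihood test (adjusted p = 0.0891, 0.0891 and 0.142), although DESeq2 called each of them. Sprr1a, Sox11 and Gap43, which are linked to axon growth, passed it. Sox11 rose 4.34-fold, from 3.60 ± 0.70 to 15.7 ± 5.28 CPM, and Gap43 rose 1.98-fold, from 285 ± 26.7 to 564 ± 124 CPM (edgeR adjusted p = 0.024 and 0.0416). In pSNL replicate 1, Atf3 reached 97.6 CPM, against 294 and 234 CPM in pSNL replicates 2 and 3.

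**Figure D1:**
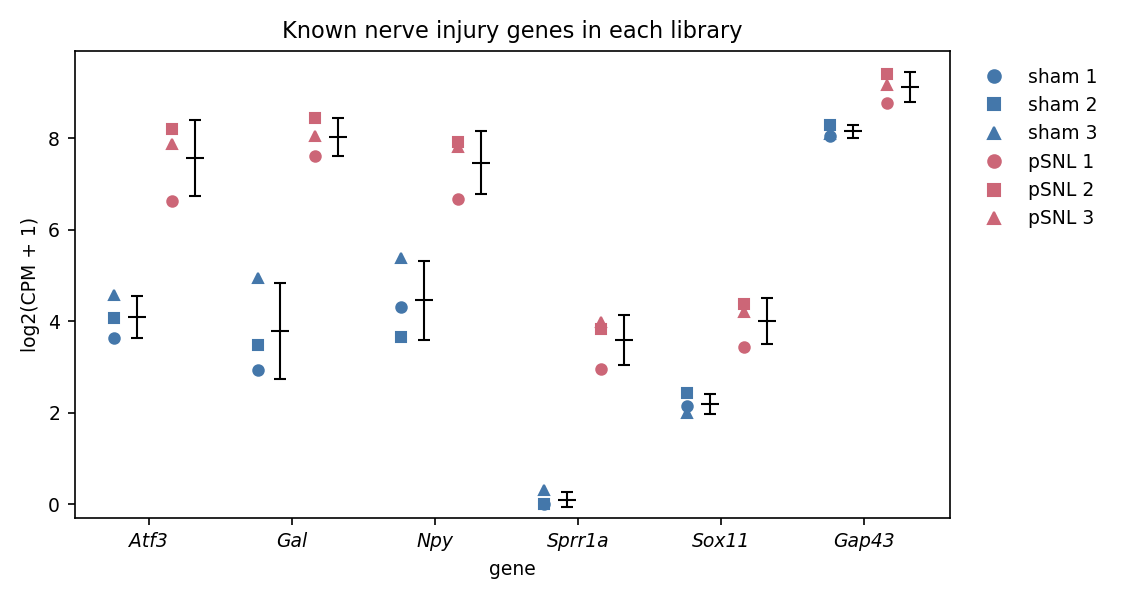
The 6 injury genes fixed as a check of the labels, in each library, as log2(CPM + 1); points are libraries, and black bars show the mean ± SD of 3 libraries on the plotted scale. For each gene the pSNL points lie above the sham points, and the pSNL replicate 1 point is the lowest of its group.

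In all, 51 genes passed the threshold of adjusted p = 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), of which 49 were higher and 2 lower in pSNL, and 34 of the 51 changed at least 2-fold. The largest rises were in genes almost silent in sham ganglia. Sprr1a (gene ID 499660), a cornified envelope protein also induced by axotomy, had 1 count over the sham libraries and 152 over the pSNL libraries, a ratio of 152 (95% counting interval 26.8 to 6034). Lce1f (gene ID 499663), another cornified envelope gene, had 3 and 156 counts, a ratio of 51.9 (17.4 to 254). The sham counts of both genes came from sham replicate 3 alone; without that library no sham count remained and both calls held (edgeR adjusted p = 0.0221 for each, where the alternatives spanned 5.53e-06 to 0.0429 for Sprr1a and 1.00e-06 to 0.130 for Lce1f). How reads of these genes were shared with close family members is uncertain. Ankrd1 (gene ID 27064), a stress-induced ankyrin repeat protein, had 3 and 132 counts (ratio 43.9, 14.7 to 216). Hamp (gene ID 84604), which encodes the iron regulator hepcidin, had 3 and 96 counts (ratio 31.95, 10.6 to 158). Of the 3 sham counts of Ankrd1 and of Hamp, 2 each came from sham replicate 3. Without that library the ratios were 87.9 (15.5 to 3499) and 63.95 (11.2 to 2552), and both calls held. Over all 6 fits with 1 library left out, Lce1f and Ankrd1 each kept the call in 3 and Hamp in 4. The peptide gene Ucn (urocortin, gene ID 29151) had 2 and 40 counts (ratio 19.97, 5.18 to 171). Without a sham library that had no count of the gene, the ratio was 101 for Sprr1a, 34.6 for Lce1f, 29.3 for Ankrd1, 21.3 for Hamp and 13.3 for Ucn.

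Crisp3 (gene ID 64827), a secreted cysteine-rich protein, rose from 0.61 ± 0.48 to 22.0 ± 6.68 CPM, a log2 fold change of 5.10 ± 0.44 (SE; edgeR adjusted p = 0.00229). The tight junction gene Cldn4 (gene ID 304407) rose from 1.15 ± 1.05 to 22.2 ± 10.5 CPM, and the cytochrome P450 gene Cyp2s1 (gene ID 308445) from 1.30 ± 1.27 to 18.8 ± 4.0 CPM (edgeR adjusted p = 0.0361 and 0.0172). The sham means of these genes were raised by sham replicate 3, where Cyp2s1 was at 2.76 CPM against 0.46 and 0.69 CPM. Without that library the log2 fold change went from 3.82 to 4.96 for Cyp2s1, from 4.24 to 5.20 for Cldn4 and from 5.10 to 5.88 for Crisp3, and the calls held. Over all 6 fits with 1 library left out, Cldn4 kept its call in 2, Cyp2s1 in 4 and Crisp3 in 6. Both genes that fell did so by less. Hcn2 (gene ID 114244), a pacemaker channel of sensory neurons, fell from 242 ± 23.6 to 154 ± 8.38 CPM (log2 fold change -0.65 ± 0.09, edgeR adjusted p = 0.0212). Mmd2 (gene ID 304301), a progestin and adipoQ receptor family member, fell from 220 ± 10.3 to 161 ± 3.05 CPM (-0.46 ± 0.08, adjusted p = 0.0397).

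The count of changed genes depended on single libraries. It was 21, 5 and 33 without sham replicates 1, 2 and 3, of which 16, 4 and 21 were among the 51, and 217, 9 and 96 without pSNL replicates 1, 2 and 3, of which 51, 6 and 24 were among them. DESeq2 called 332 genes, all 51 included. Crisp3, Sprr1a and Reg3b kept their calls whichever library was left out. No other gene named by the fixed rule passed both without sham replicate 2 and without pSNL replicate 2. Of the fits with 1 library left out, Gap43, Arg1, RT1-DMb, Cd4, Mmd2 and Ucn passed only in that without pSNL replicate 1. Across the tested genes, 2380 (21.5%) had groups that did not overlap, where chance gives 10% on average. Genes vary together between libraries, and how far that share strays by chance was not tested.

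**Figure D2:**
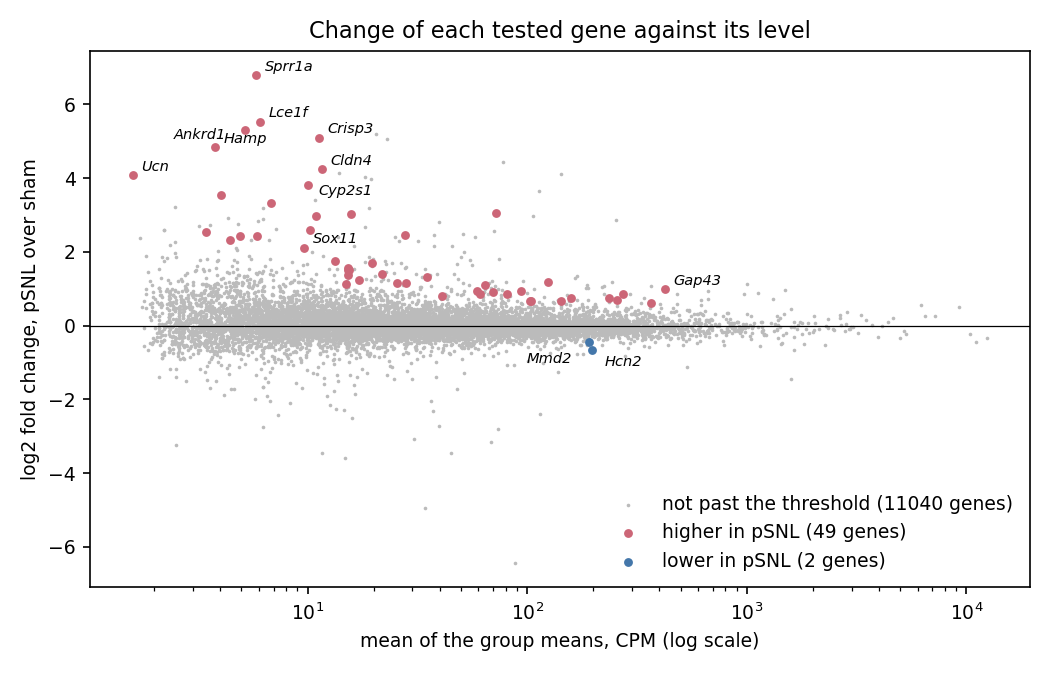
Log2 fold change of each of the 11091 tested genes, pSNL over sham, against the mean of the group means in CPM on a log axis. Red points mark the 49 genes higher in pSNL, blue points the 2 lower genes, and grey points genes that did not pass the threshold; labelled genes are those named by the fixed rule.

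The list of axotomy-responsive genes holds the 6 check genes. Of its 24 tested members 5 rose (Reg3b, Sprr1a, Sox11, Arg1 and Gap43), 19 did not pass the threshold, and 23 had a positive fold change, with a median log2 fold change of 2.20. Adjusted over the list alone, 22 were higher. Reg3b, a secreted C-type lectin of injured tissue, rose 8.14-fold, from 3.44 ± 1.15 to 28.2 ± 4.83 CPM, and Arg1 (arginase 1) rose 7.83-fold, from 2.45 ± 1.27 to 19.4 ± 9.18 CPM (edgeR adjusted p = 0.00229 and 0.0361). The list ranked above other genes in camera (adjusted p = 2.30e-21), with adjusted p = 0.290 with an estimated correlation. Its mean was 2.13 higher in pSNL on the log2 scale, and by library it was 1.55, 2.57 and 2.28 above the sham mean in pSNL replicates 1, 2 and 3 (exact permutation p = 0.1, the smallest possible).

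Among lists tested with camera, 11 ranked higher and 4 lower in pSNL with the preset correlation, none of the 15 with an estimated correlation and none by fry, whose lowest adjusted p was 0.0541 (4 and 10 lists had an unadjusted p under 0.05 in these tests). Other splits of the 6 libraries, which mix the groups, called up to 20 lists. Of the 18 lists not called with the preset correlation, 9 were called with 1 library left out (adjusted p = 0.000606 to 0.0481). These were glutamate receptors, satellite glia and central glia without sham replicate 1 or 2, the first also without pSNL replicate 2, and neurotrophic signalling and interferon response without sham replicate 2. Erythroid genes were called without sham replicate 2 or pSNL replicate 2 or 3, cell cycle genes without sham replicate 3 or pSNL replicate 2, and non-peptidergic nociceptor and cholesterol synthesis genes without pSNL replicate 1. List calls are given below with both p-values and with counts of members. The list means did not overlap between groups for 13 lists, where chance gives 3.3 on average. Lists share genes and libraries, and how far that count strays by chance was not tested. Means overlapped for the called lists of potassium channels and Schwann cell myelin (exact permutation p = 0.3 for each). They also overlapped for macrophage, cytokine and chemokine, and immediate early genes (exact permutation p = 0.2 for each).

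Of 16 tested neuropeptide precursors 1 rose (Ucn), and adjusted over the list alone 6 were higher and 1 lower. Adcyap1, which encodes PACAP, was at 43.1 ± 7.33 CPM in sham and 86.0 ± 18.7 CPM in pSNL (edgeR adjusted p = 0.0639). The list's median log2 fold change was -0.18 while its mean was 0.92 and camera's direction was upward (adjusted p = 0.0555). The median turned positive without sham replicate 3 (0.57) and without pSNL replicate 1 (0.074), and lay between -0.21 and -0.065 without each of the others.

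Of 21 tested channels of sensory transduction 1 fell (Hcn2) and none rose; adjusted over the list alone 1 was higher (Piezo1) and 2 were lower. Piezo1, a mechanosensitive channel, was at 11.7 ± 2.0 and 20.1 ± 2.86 CPM, and Tmem150c at 164 ± 25.0 and 108 ± 23.1 CPM (edgeR adjusted p = 0.0976 and 0.141). The list's median was 0.11 (-0.047 to 0.16 with 1 library left out) and camera's direction downward (adjusted p = 0.929). No potassium channel of 40 passed the threshold in edgeR's test (11 had an unadjusted p under 0.05 and DESeq2 called 3), 31 had a negative fold change, and the list ranked lower in camera (adjusted p = 0.00019; adjusted p = 0.448 with an estimated correlation). Its median log2 fold change was -0.23, and -0.40 without pSNL replicate 1. By library, the list mean minus the sham mean was 0.01, -0.21 and -0.32 in pSNL replicates 1, 2 and 3 (exact permutation p = 0.3). Kcnh2 was at 249 ± 15.5 and 192 ± 10.3 CPM (edgeR adjusted p = 0.0843) and was the only member lower when adjusted over the list alone.

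No sodium channel subunit of 13 (3 at an unadjusted p under 0.05, 1 with DESeq2) and no calcium channel subunit of 17 (4 and 1) passed the threshold in edgeR's test. Adjusted over the list alone, 1 sodium channel gene was higher (Scn3b) and 1 lower (Scn1a), and 2 calcium channel genes were higher. Cacna2d1, the α2δ-1 subunit bound by gabapentin, was at 8.80 ± 2.86 CPM in sham and 43.2 ± 24.1 CPM in pSNL (edgeR adjusted p = 0.127). Scn1a was at 154 ± 13.5 and 115 ± 15.2 CPM, and Scn3b at 83.2 ± 7.85 and 107 ± 8.90 CPM (adjusted p = 0.119 and 0.141). Neither list was called by camera (adjusted p = 0.507 and 0.328), and for sodium channels the median (0.05, and -0.23 to 0.15 with 1 library left out) and the mean (-0.02) differ in sign. None of 19 inhibitory receptor genes (5 at an unadjusted p under 0.05, 1 with DESeq2) and none of 10 glutamate receptor genes (2 and 1) passed the threshold in edgeR's test (camera adjusted p = 0.807 and 0.0555). Adjusted over the list alone, no glutamate receptor gene was called. The glutamate receptor median was -0.29, and -0.04 without sham replicate 3, the library with high central glia genes. The inhibitory receptor list had a median of -0.01 (-0.057 to 0.030 with 1 library left out) and a mean of 0.03.

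Of 13 tested markers of large, myelinated sensory neurons none passed the threshold in edgeR's test (4 at an unadjusted p under 0.05, 3 with DESeq2), 12 had a negative fold change, and 3 were lower when adjusted over the list alone (Vsnl1, Nefl and Etv1). The neurofilament gene Nefl was at 12652 ± 1369 CPM in sham and 9371 ± 604 CPM in pSNL (adjusted p = 0.101), and Vsnl1 at 347 ± 61.8 and 229 ± 25.1 CPM (adjusted p = 0.0861). The list ranked lower in camera (adjusted p = 0.00141; adjusted p = 0.290 with an estimated correlation). Among 17 pan-neuronal genes none passed the threshold in edgeR's test (6 at an unadjusted p under 0.05, 3 with DESeq2). Adjusted over the list alone 3 were lower (Snap25, Rbfox3 and Syp) and 1 higher (Stmn2), and the list was not called (camera adjusted p = 0.397; median -0.0034, and -0.083 to 0.022 with 1 library left out, mean 0.04). Snap25 was at 2147 ± 132 and 1506 ± 178 CPM and Stmn2 at 2483 ± 278 and 3212 ± 169 CPM (edgeR adjusted p = 0.0639 and 0.130). Peptidergic (9 tested) and non-peptidergic (13 tested) nociceptor markers had no member past the threshold in edgeR's test or DESeq2 (2 and 4 at an unadjusted p under 0.05, camera adjusted p = 0.530 and 0.404). Adjusted over the list alone, 2 non-peptidergic markers were higher (Il31ra and Osmr) and 1 lower (Mrgprd), with a list median of -0.15, which was -0.088 without sham replicate 1, and a mean of 0.01.

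Of 9 tested genes of the MHC class II list 2 rose (RT1-Da and RT1-DMb), and 8 were higher when adjusted over the list alone, with a median log2 fold change of 2.82. The other member, Ctss, is also in the macrophage list and had a log2 fold change of -0.15. RT1-Db2, a class II gene outside the list, also rose, from 1.45 ± 0.53 to 7.42 ± 1.32 CPM (edgeR adjusted p = 0.0264). Of the fits with 1 library left out, it passed only in that without pSNL replicate 1. RT1-Da rose 8.32-fold, from 15.4 ± 1.97 to 128 ± 42.5 CPM, and RT1-DMb 3.39-fold, from 6.04 ± 0.73 to 20.6 ± 6.96 CPM (edgeR adjusted p = 0.0172 and 0.0299). Ciita, the class II transactivator, was at 1.45 ± 0.53 and 11.04 ± 6.18 CPM (adjusted p = 0.0504). The list ranked above other genes (camera adjusted p = 4.25e-10; adjusted p = 0.290 with an estimated correlation). RT1 class II genes are close paralogs, so how their reads were shared between copies is uncertain.

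No macrophage marker of 22 passed the threshold in edgeR's test (13 at an unadjusted p under 0.05, 5 with DESeq2), 20 had a positive fold change with a median of 0.81, and 7 were higher when adjusted over the list alone. Lyz2 was at 95.7 ± 13.9 and 243 ± 66.8 CPM and Cd68 at 3.37 ± 1.04 and 9.09 ± 1.93 CPM (edgeR adjusted p = 0.0639 and 0.082). The list ranked higher in camera (adjusted p = 2.53e-09; adjusted p = 0.399 with an estimated correlation), although its mean in sham replicate 3 (3.37) exceeded that in pSNL replicate 1 (3.33). Of 20 complement genes 1 rose (C1s, 20.04 ± 4.79 to 49.9 ± 10.8 CPM, edgeR adjusted p = 0.0299) and 9 were higher when adjusted over the list alone (camera adjusted p = 5.13e-08; adjusted p = 0.290 with an estimated correlation). None of 15 cytokine and chemokine genes passed the threshold in edgeR's test (6 at an unadjusted p under 0.05, 4 with DESeq2) and 4 were higher when adjusted over the list alone (Csf2rb, Ccl2, Csf1 and Il33). Csf1, a growth factor of macrophages and microglia, was at 21.7 ± 8.80 and 78.6 ± 20.97 CPM (edgeR adjusted p = 0.0823). That list ranked higher in camera (adjusted p = 0.00044; adjusted p = 0.290 with an estimated correlation). Its median log2 fold change was 0.29 and lay between 0.49 and 0.69 without sham replicate 1 (0.53), 2 (0.49) or 3 (0.69), or pSNL replicate 1 (0.67) or 3 (0.51).

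Only 2 of the T and NK cell genes were tested. Cd4, which rat macrophages also carry, rose from 10.3 ± 1.25 to 24.0 ± 5.52 CPM (edgeR adjusted p = 0.0363), and Lck was at 1.91 ± 0.58 and 2.30 ± 1.20 CPM (adjusted p = 0.853). Interferon-stimulated genes (24 tested) had none past the threshold in edgeR's test or DESeq2 (2 at an unadjusted p under 0.05, camera adjusted p = 0.0936). Of neutrophil and mast cell genes 2 were tested and neither was called by edgeR or DESeq2 or had an unadjusted p under 0.05. No B cell gene passed the filter for testing, and the summed level of the B cell list was 2.8 to 5.9 CPM per library.

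All 17 tested fibroblast and matrix genes had a positive fold change, 1 rose over all genes (Mgp, matrix Gla protein, 43.4 ± 4.95 to 78.8 ± 7.47 CPM, edgeR adjusted p = 0.0172), and 11 were higher when adjusted over the list alone. Fibronectin (Fn1) was at 71.5 ± 9.59 and 142 ± 34.8 CPM and lumican (Lum) at 64.5 ± 16.5 and 122 ± 15.5 CPM (adjusted p = 0.0576 and 0.0662). Of 18 matrix proteases and inhibitors 1 rose (Timp1, 40.5 ± 4.47 to 78.0 ± 12.5 CPM, adjusted p = 0.0226) and 9 were higher when adjusted over the list alone. Both lists ranked higher in camera (adjusted p = 4.25e-10 and 6.93e-06; adjusted p = 0.290 with an estimated correlation for each). The protease list's median was 0.54, and 0.85 without sham replicate 3.

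**Figure D3:**
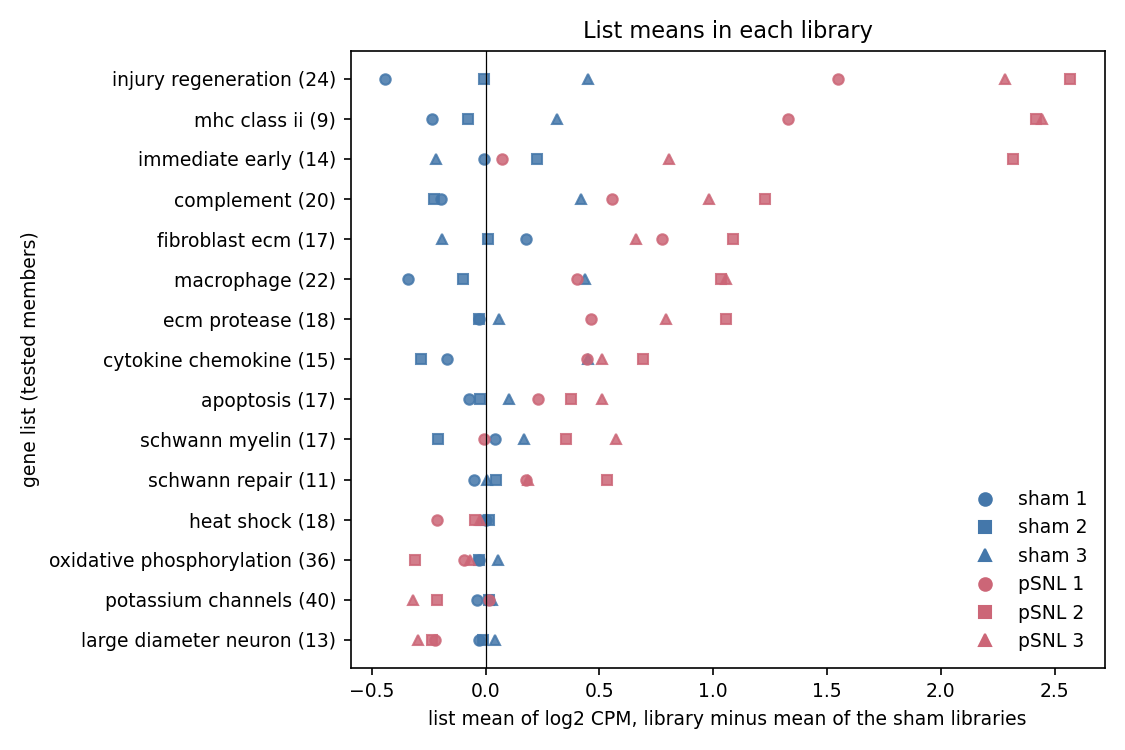
Mean log2 CPM over the tested members of each of the 15 lists called by camera with its preset correlation, in each library, minus the mean of the 3 sham libraries; the number of tested members stands in brackets. Injury and MHC class II genes lay at least 1.33 above the sham mean in each pSNL library, while immediate early genes were 2.32 above it in pSNL replicate 2 and 0.07 in pSNL replicate 1.

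No Schwann cell myelin gene of 17 passed the threshold in edgeR's test (7 at an unadjusted p under 0.05, 3 with DESeq2), and 2 were higher when adjusted over the list alone (Drp2 and Prx). Periaxin (Prx) was at 995 ± 236 and 1643 ± 252 CPM (edgeR adjusted p = 0.132). Mbp was at 9933 CPM in sham replicate 3 and at 3242 to 5765 CPM in the others. The list ranked higher in camera (adjusted p = 0.00451; adjusted p = 0.477 with an estimated correlation; 8.37e-06 to 0.477 over the alternatives). The call was lost without sham replicate 2 (adjusted p = 0.0527) and without pSNL replicate 3 (adjusted p = 0.161, median 0.23 against 0.40). By library, the list mean lay 0.36 and 0.57 above the sham mean in pSNL replicates 2 and 3. In pSNL replicate 1 it was not above the sham mean (exact permutation p = 0.3). Of 11 genes of repair Schwann cells 1 rose (Gap43, also an injury gene of neurons), 3 were higher and 1 lower (Sox2) when adjusted over the list alone, and the camera call (adjusted p = 0.0408; adjusted p = 0.456 with an estimated correlation) was lost without sham replicate 1 (0.0672), without pSNL replicate 2 (0.103, median 0.12 against 0.27), without a filter (0.142) and from DESeq2's statistics (0.0596), with adjusted p between 0.0174 and 0.456 over the alternatives. Without pSNL replicate 1 its median was 0.41. Satellite glia markers (17 tested) had none past the threshold in edgeR's test (6 at an unadjusted p under 0.05, 3 with DESeq2), a median of -0.53, which was -0.04 without sham replicate 3, and a camera adjusted p of 0.106.

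Sham replicate 3 stood apart in glial genes. Mobp, a myelin gene of oligodendrocytes, was at 519 CPM there and at 1.6 to 3.2 CPM in the others. Gfap was at 542 CPM against 18.1 to 50.9 CPM. Of the 7 tested genes of central glia none passed the threshold in edgeR's test or DESeq2 (1 at an unadjusted p under 0.05), and the list mean was 6.06 in this library and 2.94 to 3.20 in the others (camera adjusted p = 0.124 for pSNL against sham). Skeletal muscle genes were high in replicate 3 of both groups. Ckm was at 85.5 CPM in sham replicate 3 and 161 CPM in pSNL replicate 3, and at most 2.8 CPM elsewhere. The muscle list (5 tested, none past the threshold in edgeR's test or DESeq2 and 0 at an unadjusted p under 0.05) had a median of 0.87 (-2.85 to 3.80 with 1 library left out) and a downward camera direction (adjusted p = 0.954); its member Pvalb is also a marker of proprioceptive neurons. With replicate 3 of both groups left out, a fit chosen after seeing the data, 102 genes were called (94 higher, 8 lower), of which 20 were among the 51. Haemoglobin genes varied within both groups, from 423 CPM (pSNL replicate 1) to 2796 CPM (sham replicate 3) for Hbb, and none of 8 erythroid genes passed the threshold in edgeR's test or DESeq2, with 0 at an unadjusted p under 0.05 (camera adjusted p = 0.0803). Endothelial and mural markers (17 tested) had none past the threshold in edgeR's test or DESeq2 and 0 at an unadjusted p under 0.05 (camera adjusted p = 0.693). Of 3 tested adipocyte genes none passed the threshold in edgeR's test (2 at an unadjusted p under 0.05, 1 with DESeq2) and 2 were higher when adjusted over the list alone (Cidec and Lpl).

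**Figure D4:**
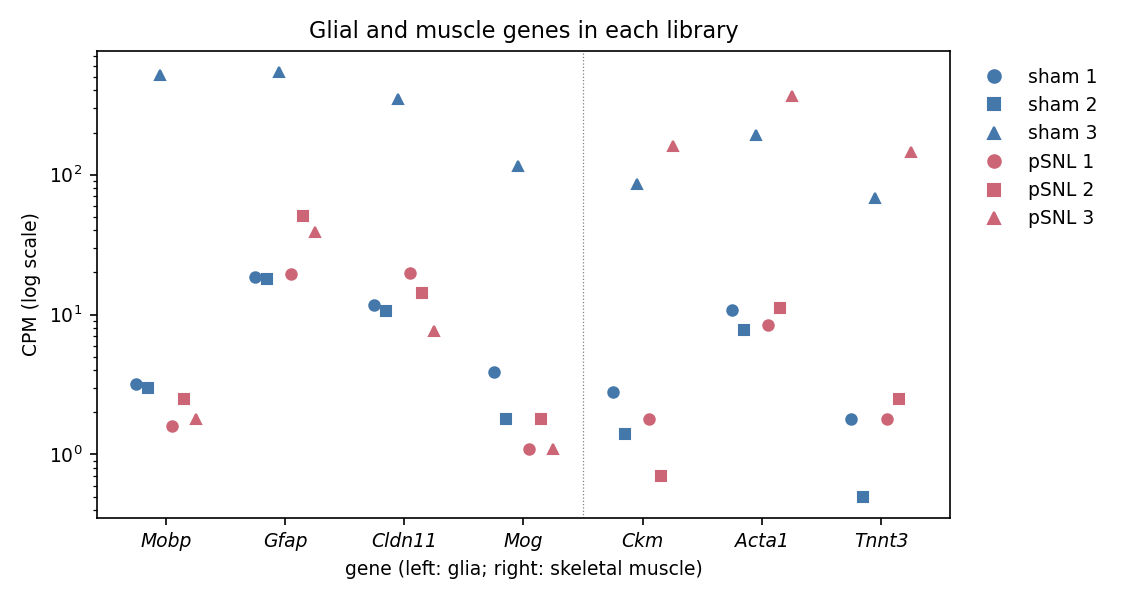
CPM on a log axis of 4 glial genes and 3 skeletal muscle genes in each library; each point is a library. Sham replicate 3 lies above the others for the glial genes, with 519 CPM of Mobp, and replicate 3 of both groups lies above the rest for the muscle genes.

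Among cell state lists, all 14 immediate early genes had a positive fold change, none passed the threshold in edgeR's test or DESeq2 (3 at an unadjusted p under 0.05), and 0 were higher when adjusted over the list alone. Their summed level was 2053 CPM in pSNL replicate 2, 558 CPM in pSNL replicate 3 and 215 to 308 CPM in the others. The list ranked higher in camera (adjusted p = 9.51e-05; adjusted p = 0.456 with an estimated correlation), with a median of 1.43, and 0.41 without pSNL replicate 2. None of 36 nuclear genes of the respiratory chain passed the threshold in edgeR's test (11 at an unadjusted p under 0.05, 2 with DESeq2) and 35 had a negative fold change, with a median of -0.15 (camera adjusted p = 5.17e-06; adjusted p = 0.506 with an estimated correlation), and -0.08 without pSNL replicate 2. No heat shock gene of 18 passed the threshold in edgeR's test (5 at an unadjusted p under 0.05, 2 with DESeq2). Hspb1 was at 343 ± 52.5 and 624 ± 137 CPM and Hspa5 at 576 ± 31.6 and 449 ± 33.4 CPM (edgeR adjusted p = 0.0887 and 0.0976), the former higher and the latter lower when adjusted over the list alone. That list's downward call (camera adjusted p = 0.0164; adjusted p = 0.456 with an estimated correlation) was lost without sham replicate 1 (0.0994), sham replicate 2 (0.085) or pSNL replicate 1 (0.418, median -0.10 against -0.15), with adjusted p between 0.00682 and 0.456 over the alternatives.

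Of 17 apoptosis and p53 target genes none passed the threshold in edgeR's test (5 at an unadjusted p under 0.05, 1 with DESeq2) and 4 were higher when adjusted over the list alone. Cdkn1a was at 8.19 ± 2.46 and 29.9 ± 10.9 CPM (edgeR adjusted p = 0.0639). The list's camera call (adjusted p = 0.00451; adjusted p = 0.290 with an estimated correlation) was lost without pSNL replicate 3 (0.0703, with 0.00172 to 0.290 over the alternatives), and its median of 0.23 was 0.37 without pSNL replicate 1. Cell cycle genes (17 tested, camera adjusted p = 0.0553), cholesterol synthesis genes (24 tested, 0.124) and genes of neurotrophic signalling (21 tested, 0.0803) had no member past the threshold in edgeR's test (4, 3 and 9 at an unadjusted p under 0.05 and 1, 1 and 2 with DESeq2). Adjusted over the list alone, 1 cell cycle gene was higher (Mcm5).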

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

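The fit without robust dispersion and the fit without replicate 3 of both groups were chosen after the data were seen. For 148 genes, 51 of them called, 2212 values were computed under the alternatives. Of these 1875 held direction and side of the threshold, 224 lost a call, 105 gained a call and 8 reversed, none of the latter in a called gene. For the 33 lists, 433 of 527 values held, 40 lost a call, 28 gained a call and 26 reversed, none of the latter in a called list. Scaling moved the median log2 fold change of all genes by under 0.1. Depth limits genes of a few CPM, where 1 CPM is 4.31 to 4.42 counts.

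The 51 changed genes became 89 without a filter (76 higher, 13 lower), 332 with DESeq2 (250 and 82), 102 without replicate 3 of both groups and 258 at an adjusted p of 0.1. The fits that left out 1 library called 5 to 217 genes, fewest without sham replicate 2 and most without pSNL replicate 1. List members changed went from 13 to 20 without a filter, 84 with DESeq2, 27 without robust dispersion, and 2 to 61 with 1 library left out. The 15 called lists became 0 with an estimated correlation and 0 by fry, and 14 to 19 with 1 library left out. The 13 lists with separate means became 22 without replicate 3 of both groups, and 12 to 20 with 1 library left out. Fewer libraries and other spread estimates enter these fits; beyond that, the cause was not tested.

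The replicate numbers are not stated to pair animals, and deviations of same-numbered libraries correlated at 0.032, 0.011 and 0.123, so the numbers were not taken to pair the libraries, and only replicate 3 correlated best with its own number. The replicate block gave 111 genes (107 higher, 4 lower; 47 of the 51) and 36 list members. Under the block the camera direction of sensory transduction (median 0.11) and skeletal muscle (0.57) turned.

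Other reversals, none past a threshold, were these. A list counts as reversed where the direction of its test turned, even where its median kept its sign. With DESeq2, skeletal muscle had a list median of 0.87, and by fry skeletal muscle 0.87 and inhibitory receptors -0.0063. Without replicate 3 of both groups, Lck was at -0.16 and Cldn11 at 0.61, and list medians were 0.018 for sensory transduction, 0.10 for inhibitory receptors, -0.0027 for glutamate receptors and for cholesterol synthesis, 0.027 for interferon response and 0.26 for central glia. With 1 library left out, log2 fold changes ranged from -3.43 to 5.41 for Tnnt3, -0.22 to 1.22 for Myh7, -2.85 to 3.80 for Acta1, -3.70 to 0.31 for Cldn11 and -1.16 to 0.18 for Aldh1l1. List medians, whose camera direction turned in at least 1 of these fits, ranged from -0.23 to 0.15 for sodium channels, -0.047 to 0.16 for sensory transduction, -0.057 to 0.030 for inhibitory receptors, -0.37 to -0.11 for peptidergic nociceptors, -0.083 to 0.022 for pan-neuronal genes, 0.011 to 0.37 for interferon response, -0.056 to 0.16 for endothelium, -2.85 to 3.80 for skeletal muscle and -1.42 to 0.31 for central glia. The cause of these reversals was not tested, except that central glia and muscle genes follow sham replicate 3 and pSNL replicate 3, as their values per library show.

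The planned pseudocount and low-value filter for normalized values do not apply to counts and were not run, nor was limma-trend for the lists, since camera already works on log2 CPM.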

Other observations

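All tests of explanations below were chosen after the result was seen. Of the 51 called genes, 13 are in the fixed lists. The genes named next are not, and were chosen after their values were seen. Tgfbi, a matrix protein, rose from 75.8 ± 8.29 to 173 ± 44.1 CPM, Bgn (biglycan) from 80.6 ± 5.29 to 127 ± 10.9 CPM, Ssc5d from 41.01 ± 0.75 to 87.6 ± 15.6 CPM, and the heparan sulfate proteoglycan Sdc1 from 8.49 ± 0.46 to 46.98 ± 13.98 CPM (edgeR, SD, n = 3 each). The C-type lectin genes Clec7a (0.61 ± 0.48 to 7.42 ± 2.73 CPM) and Clec10a (8.03 ± 1.22 to 22.8 ± 5.85 CPM) rose. Without sham replicate 2 the log2 fold change of Clec7a went from 3.54 to 4.32 and its call was lost. Tspo, a mitochondrial protein used as an imaging target in neuroinflammation, rose from 7.73 ± 0.52 to 22.7 ± 6.86 CPM. Tph2, the neuronal enzyme of serotonin synthesis, rose from 9.26 ± 1.19 to 30.01 ± 11.6 CPM, and the clock gene Per1 from 63.6 ± 4.98 to 123 ± 22.4 CPM. Of these genes, Sdc1 and Ssc5d lost their calls only without sham replicate 2. Clec7a, Tspo, Tph2 and Per1 kept theirs in 1 of the 6 such fits, that without pSNL replicate 1, and Tgfbi, Bgn and Clec10a in 2.

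For the 51 changed genes, the highest count in the other splits of the 6 libraries into 3 and 3 was 0, and 1 of the 10 splits, the real one, reached 51. For the 15 called lists, 3 of the 10 splits reached as many, the highest other being 20, with sham replicates 1 and 2 and pSNL replicate 1 set against the rest; a split with sham replicates 1 and 3 and pSNL replicate 1 called 17. The splits number 10, too few for a share under 0.05 in either case.

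Central glia genes in sham replicate 3 form the first pattern. A pSNL library under a sham label is argued against, since on the injury list mean this library lies at 0.287 of the way from the other sham libraries to the pSNL mean, below the lowest pSNL library at 0.752. pSNL RNA is argued against as the source of these genes. The 7 tested were each higher in this library than in the highest pSNL library, by a median of 1.45 (log2). The pattern was itself that these genes were highest here, so this comparison restates it and is no separate test. Whether some pSNL RNA is present besides stays open. Of 24 tested injury genes, 14 were at least 4 times higher in pSNL than in the other sham libraries. In sham replicate 3 these 14 showed a median of 8.02% of that difference (quartiles 2.65% and 14.1%). Spinal cord or root tissue in this sample is a candidate explanation: the median of the 7 tested central glia genes is 2.20 higher (log2) than in the other sham libraries, with Mobp at 519 CPM and Mog at 116 CPM, although Mag is also a Schwann cell gene. These values restate the pattern as well, so they are no separate test of this explanation. No biological explanation was tested.

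Cornified envelope genes Sprr1a and Lce1f higher in pSNL are the second pattern. Skin in the pSNL samples is argued against: Krt1, Krt5, Krt10 and Krt14 together were 0.29 CPM higher in pSNL (3.21 ± 0.83 to 3.51 ± 1.28), against 23.3 CPM for the pair. Reads shared with a near-identical annotated gene stay open: 0 of the 8 estimated counts above 0 of the pair are fractional (tolerance 0.005). However, 89.3% of all listed values are whole, and 8 values would all be whole with a chance of 40.4% at that share. Sprr1a is known from axotomized neurons, and a shared response of Lce1f to the ligation may be a hypothesis for follow-up; which cells carry it was not tested, and in situ hybridisation for Lce1f with a probe unique to it, not done here, would decide.

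MHC class II genes differed more between the groups than macrophage markers, the third pattern. The mean log2 CPM of 8 class II genes minus that of 21 macrophage markers was 1.44 higher in pSNL (SE 0.20, exact permutation p = 0.1, the smallest possible). Ctss, a member of both lists, was left out. The values were 0.23 to 0.59 in sham and 1.55 to 2.07 in pSNL. If macrophages alone carried these genes, more macrophages of unchanged make-up would by themselves raise both sets alike, which these values argue against. The pattern was picked for this difference, though, so the difference restates it and is no separate test. The macrophage markers themselves did not rise alike (log2 fold change -0.55 for Cd163 to 2.38 for Fcgr2b). Which cells carry them was not tested. Central tissue in sham replicate 3 is argued against, as the difference was 1.33 without that library, and so are reads shared between RT1 class II paralogs as the whole cause. Cd74 and Ciita, which are not RT1 genes and did not pass the threshold (edgeR adjusted p = 0.0639 and 0.0504), had fitted log2 fold changes of 2.86 ± 0.37 and 2.90 ± 0.51 (SE), on average 2.06 above the median macrophage marker at 0.82. RT1-DMa, the lowest of the 8 class II genes, was at 0.95 ± 0.23 (SE), near that median. Higher class II expression per cell after ligation may be a hypothesis for follow-up, but entry of another class II positive cell type could give the same difference, and class II staining together with cell type markers, not done here, would decide.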
